A study of Mus musculus with 10 samples.

How the data were processed

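Gene expression was measured on Illumina MouseRef-8 bead arrays in motor neurons carrying an Hb9::GFP reporter, in which a motor neuron promoter drives green fluorescent protein. The cells came from 3 origins: the spinal cord of embryos at embryonic day 13.5, cultures differentiated from the mouse embryonic stem (ES) cell line V6.5, and embryonic fibroblasts reprogrammed with 10 transcription factors that the labels do not name. Cells of each origin were sorted into GFP-high and GFP-medium fractions. Each gate held 2 arrays for the embryonic and ES-derived cells and 1 array for the induced (reprogrammed) cells, which gives 10 arrays in 6 groups. Groups and replicate numbers were taken from the sample labels. Per the labels, RNA was extracted with Trizol and amplified in a pair of rounds before biotin labelling. Nothing in the labels says that replicates were separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

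The deposited non-normalized table holds 1 linear intensity per probe and array, exported from BeadStudio (no version given) per the submitters' processing notes. Values below 0 in that table show that background had been subtracted within each array before deposit. The authors also deposited a detection p-value for each probe on each array, per the file headers. A further deposited table holds intensity on a linear scale after the authors' normalization between arrays. Its array medians lay near 13.6, its first array was identical to the non-normalized table, and probe ranks within each array were the same. The normalization method is not given in the sources used here. The table was used only as an alternative.

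Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none in the platform annotation given. Symbols in that annotation can be old. The values were corrected with normexp from limma 3.58.1 in R 4.3.3, using the detection p-values and an offset of 16, then brought to log2 and quantile normalized. This step had been chosen for a table without background correction. It was kept because its fitted background mean absorbs a constant subtracted from an array, and the same normalization without it is among the alternatives. Probes with a detection p under 0.01 on at least 2 arrays were kept, which left 11915. For each gene the probe with the highest mean over all arrays was used, giving 9679 features: 8967 genes and 712 unnamed probes. More than 1 kept probe measured 1790 genes. Among called genes with several probes, Cxcl12 (1 of 19, ES-derived against embryonic) and Luc7l (1 of 20, induced against embryonic) had probes of opposite sign.

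Differences between origins and between gates were fitted with limma (lmFit and eBayes, two-sided) in an additive model of origin and gate over all 10 arrays, with 6 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Whether the gate difference changed with origin was tested on the 6 group means, with 4 residual degrees of freedom. The comparisons with induced cells rest on 2 arrays for that origin. Differences are on the log2 scale and follow as value ± SE. A gene that was not detected on any array of a group, by any of its probes or by the probe used, has only a bound there. For genes of this kind a fold is given as at least N: the mean of the brighter group against the mean, over the arrays of the other group, of the higher of the gene's own value and the lowest value among detected probes.

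The 26 gene lists, the named-genes rule, the tests and most alternatives were fixed before the data were examined. The rule took, per comparison, up to 6 genes with the largest rise and 6 with the largest fall among called genes with non-overlapping groups and an established symbol. It added up to 4 called members of each list, or up to 2 members as values where none was called, and 6 genes always (Mnx1, Isl1, Lhx3, Chat, Slc18a3 and Tubb3). Slc18a3 was not tested, since no probe of it passed the detection filter. Lists were tested with camera at its preset correlation of 0.01 and adjusted over the 26 lists of a comparison. An estimated correlation was the alternative. The fry test, run beside it, asks whether the genes of a set move, on balance, in 1 direction and, in its mixed form, whether they change in either direction. Neither form compares the set with other genes. In the ribosomal list, 4 symbols name kinases or binding proteins.

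On simulated data with 200 changed genes among 9679, the additive fit recovered 1.49% of log2 changes of 1, 22.4% of changes of 2 and 81.8% of changes of 4 for ES-derived against embryonic cells. For induced against embryonic cells these shares were 0%, 11.9% and 69.7%. For induced against ES-derived cells they were 0%, 22.4% and 68.2%, and for the gates 5.97%, 50.7% and 90.9%. Falsely called genes numbered 5, 3, 6 and 4. The test of the gate difference between ES-derived and embryonic cells recovered 0% of log2 changes of 4 and 87.5% of changes of 8. The number of arrays limits the precision: the median SE of a log2 difference was 0.477 for ES-derived against embryonic cells, 0.584 for both comparisons with induced cells and 0.426 for the gates.

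The alternatives were no background correction, median scaling, the authors' values, other detection filters, all probes, a trended and robust variance, array weights, a fold threshold, single gates, gate means as replicates, fewer origins, replicate blocks and leaving out each array. After the data were seen, fits without the 3 arrays of mean intensity under 100 were added. Values not detected were also set to the lowest detected value of their array, where the text says so, a choice made after the data were seen as well. No coordinates were used, and no array columns of other samples were present (0).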

Results

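The 10 arrays compared sorted motor neurons of embryonic, ES-derived and induced origin, with 4, 4 and 2 arrays. Brightness differed widely between arrays. Mean deposited intensity on the embryonic arrays was 474 and 282 for the GFP-high replicates 1 and 2, and 51.3 and 352 for the GFP-medium ones. On the ES-derived arrays it was 3.16 and 575 for GFP-high and 81.6 and 577.2 for GFP-medium, and on the induced arrays it was 166 for GFP-high and 140 for GFP-medium. ES-derived GFP-high replicate 1 detected 2095 probes, against 6921 to 11441 on the other 9 arrays. Its median correlation across genes with the other arrays was 0.587, and that of the other arrays lay between 0.795 and 0.888. The lowest detected log2 value on it was 8.68, so that low transcripts could not be measured there. Results are therefore also given without this array, and without the 3 arrays of mean intensity under 100 (this array, ES-derived GFP-medium replicate 1 and embryonic GFP-medium replicate 1), a choice made after the data were seen.

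**Figure D1:**
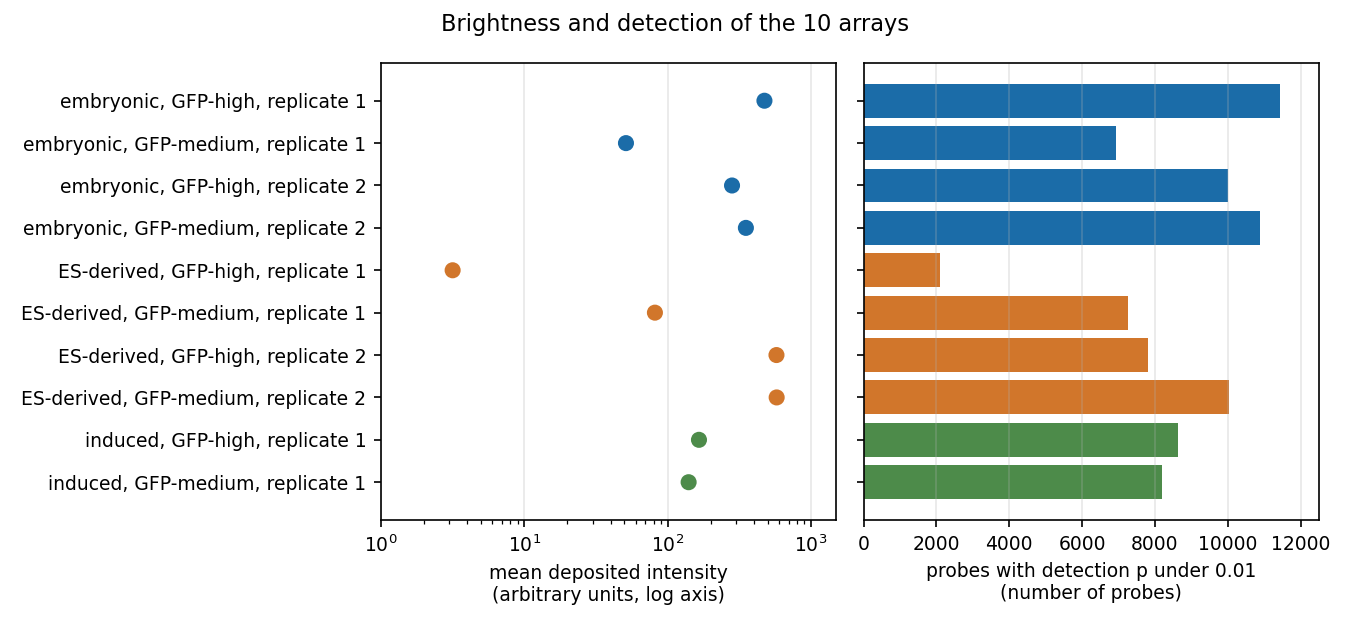
Mean deposited intensity (log axis) and number of probes detected for each of the 10 arrays. ES-derived GFP-high replicate 1 is the dimmest, with a mean of 3.16 and 2095 probes.

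The first comparison asked how motor neurons made from ES cells differ from those of the embryo. In ES-derived cells the muscle list (6 of 14 members called) and the blood list (3 of 12, all globins) were lower and the glycolysis and hypoxia list (3 of 17) was higher, also with an estimated correlation. The mesenchymal list (7 of 26 called) and the Hox lists of paralogs 6 to 9 (3 of 9) and 10 to 13 (2 of 6) were called lower with the preset correlation only (adjusted p = 0.0697, 0.0937 and 0.0697 with an estimated correlation). Myl1, a myosin light chain of fast muscle, fell (adjusted p = 5.37e-05), by 25.1-fold with values not detected set to the lowest detected value of their array, and Hoxd10, which patterns the lumbar cord, was at least 20.7-fold lower (adjusted p = 7.26e-05). Mt1, a metal-binding metallothionein, rose by 4.40 ± 0.61 (adjusted p = 0.0103), and the glucose transporter gene Slc2a1 rose by 3.49 ± 0.47 (adjusted p = 0.00947). Of 9679 features, 87 were called, 8 higher and 79 lower. The arrays of both origins did not overlap for any of the 87, as for 7.30% of all genes. Without ES-derived GFP-high replicate 1 the count was 270 (94 higher, 176 lower), which held all 87, and without the 3 dimmest arrays it was 409 (155 higher, 254 lower), which held 82 of them.

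Among the 14 skeletal and smooth muscle genes measured, 6 fell (11 adjusted over the list alone), with a list median of -3.31, or -2.50 with genes at their bound (camera adjusted p = 2.04e-17). Besides Myl1 they included the embryonic and perinatal contractile genes Myh8 (14.8-fold lower by the same rule as Myl1) and Actc1 (at least 11.2-fold lower) and the troponin gene Tnnc2 (at least 4.25-fold lower). Of 26 fibroblast and mesenchymal genes, 7 fell (19 adjusted over the list alone; median -1.70, at bounds -1.42; camera adjusted p = 5.21e-17; adjusted p = 0.0697 with an estimated correlation). Examples of the mesenchymal genes were the growth factor receptor gene Pdgfra (-4.40 ± 0.71), the collagen gene Col5a1 (-4.02 ± 0.64), the proteoglycan gene Bgn (-3.63 ± 0.46) and the matrix protease gene Mmp2 (-3.62 ± 0.58). By the same rule as Myl1 these stood at -3.52, -2.92, -2.41 and -2.52, in this order. Of 12 blood, endothelial and microglial genes, 3 fell (4 adjusted over the list alone; median -0.77, at bounds 0; camera adjusted p = 3.81e-05). All 3 were globins, with Hbb-y at least 11.4-fold, Hba-a1 at least 4.55-fold and Hbb-bh1 at least 1.29-fold lower. Muscle, mesenchymal and globin genes are markers of tissues other than neurons, and the named ones were detected on all 4 embryonic arrays. On the ES-derived arrays the probes of Myl1, Myh8 and Bgn were detected on 1 and those of Pdgfra, Col5a1 and Mmp2 on 3.

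Hox genes were tested in 3 lists by their position in the clusters. Of 9 measured paralogs 6 to 9, 3 fell (4 adjusted over the list alone), with Hoxc9 at -4.57 ± 0.59, Hoxa7 at -3.13 ± 0.55 (each detected on 3 ES-derived arrays) and Hoxc6 at -2.37 ± 0.42 (list median -1.37; camera adjusted p = 3.90e-05; adjusted p = 0.0937 with an estimated correlation). Of 6 paralogs 10 to 13, 2 fell (3 adjusted over the list alone), Hoxd10 and Hoxc10 (at least 1.67-fold lower), with a median of -0.87, at bounds 0 (camera adjusted p = 0.00351; adjusted p = 0.0697 with an estimated correlation). The call of the latter list was lost with no filter on dim probes (adjusted p = 0.158). No member of the 12 paralogs 1 to 5 was called (0 adjusted over the list alone). That list had a median of 0.31 and a camera adjusted p of 0.0197 (adjusted p = 0.50 with an estimated correlation), with Hoxa5 at 2.00 ± 0.56 and Hoxb3 at -1.86 ± 1.00. It was not called without embryonic GFP-high replicate 2 (adjusted p = 0.106), ES-derived GFP-high replicate 2 (0.152) or ES-derived GFP-medium replicate 2 (0.214), nor with no filter (0.184).

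Of 17 glycolysis and hypoxia genes, 3 rose (6 higher and 1 lower adjusted over the list alone; median 0.86; camera adjusted p = 2.83e-09). They were Slc2a1, a further glucose transporter gene, Slc2a3 (2.81 ± 0.46), and the phosphofructokinase gene Pfkl (2.54 ± 0.39). The mitochondrial protein gene Mgarp (3.77 ± 0.46, detected on 2 embryonic arrays) and the tight junction gene Cldn12 (2.47 ± 0.47, adjusted p = 0.0493) also rose. Of 12 pluripotency genes, 0 were called (4 higher adjusted over the list alone), with a median of 2.51, at bounds 2.30 (camera adjusted p = 3.26e-06; adjusted p = 0.241 with an estimated correlation). Dppa5a stood at 4.43 ± 1.11 and Dppa4 at 4.39 ± 1.06. These genes varied between the ES-derived arrays, where the SD of Dppa4 was 2.62 (n = 4), and GFP-medium replicate 1 had the highest values. Without the dimmest array, and without the 3 dimmest, 3 members were called higher: Dnmt3l, Lin28a and Sall4.

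The motor neuron transcription factor, cholinergic and motor column lists were not called. The ion channel and receptor list was called lower with the preset correlation only. Of 8 motor neuron transcription factors, 0 were called (camera adjusted p = 0.728), with Isl1 at -0.56 ± 1.16 and Lhx3 at 0.60 ± 0.55. Mnx1, the gene of Hb9 itself, was not detected on any embryonic or ES-derived array. These cells were sorted on an Hb9 reporter, so the missing detection does not show that the transcript was absent. Chat, which makes acetylcholine, stood at 0.67 ± 0.91, and the 11 cholinergic and effector genes had 0 calls over all genes and 1 lower over the list alone (camera adjusted p = 0.265). In the motor column list of 12 genes the adhesion gene Alcam fell (-2.94 ± 0.50; 4 lower adjusted over the list alone; camera adjusted p = 0.197). The ion channel and receptor list held 1 call of 12 (1 adjusted over the list alone), the AMPA receptor gene Gria1. Gria1 stood at -2.59 ± 0.39 and was detected on 1 ES-derived array. With values not detected set to the lowest detected value of their array it stood at -1.06. The list had a median of -0.48, at bounds -0.30 (camera adjusted p = 0.0386, and adjusted p = 0.253 with an estimated correlation). That call was lost without embryonic GFP-medium replicate 1 (adjusted p = 0.0579) or 2 (0.0919), ES-derived GFP-medium replicate 1 (0.1995) or 2 (0.0736) and ES-derived GFP-high replicate 2 (0.0925). It was also lost without the 3 dimmest arrays (0.0860).

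Other neural lists were not called with all arrays and the detection filter. Their camera adjusted p was 0.177 for 19 pan-neuronal, 0.825 for 14 synaptic, 0.730 for 16 neural progenitor and 0.293 for 13 other spinal neuron genes. It was 0.382 for 9 glial genes (1 higher and 1 lower adjusted over the list alone) and 0.215 for 7 transcription factors used in reprogramming. Of the glial genes the glutamate transporter gene Slc1a3, detected on 3 ES-derived arrays, was called lower (-3.68 ± 0.51). With values not detected set to the lowest detected value of their array it stood at -2.65. Tubb3 was detected on 0 ES-derived and 2 embryonic arrays. The pan-neuronal list was called lower with no filter on dim probes (adjusted p = 0.0218), without embryonic GFP-high replicate 1 (0.0259), without ES-derived GFP-high replicate 1 (5.94e-05) and without the 3 dimmest arrays (0.0431). The other spinal neuron list was called lower without embryonic GFP-medium replicate 1 (adjusted p = 0.0136) and without the 3 dimmest arrays (0.00636). The reprogramming list was called higher without ES-derived GFP-medium replicate 1 (0.0143) and without the 3 dimmest arrays (0.0437). The cell cycle list had an adjusted p of 0.722 over 27 genes. It was called lower without the 3 dimmest arrays (adjusted p = 0.00739). Lists whose median, mean and test differed in sign were neural progenitor, cell cycle, reprogramming and interferon genes.

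In this comparison 12 of 26 lists were called, 3 with the estimated correlation (muscle, adjusted p = 0.0154; blood, 0.0326; glycolysis, 0.0131) and 9 with fry. The limma counts without 1 array were 35 (embryonic GFP-high replicate 1), 41 (embryonic GFP-high replicate 2), 35 (embryonic GFP-medium replicate 2), 270 (ES-derived GFP-high replicate 1) and 55 (either induced array). They were 40 with median scaling, 550 with array weights and 0 with gate means as replicates. The median log2 difference of all genes was -0.13, and 0.13 with median scaling, -0.29 with the authors' values and -0.19 without background correction.

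**Figure D2:**
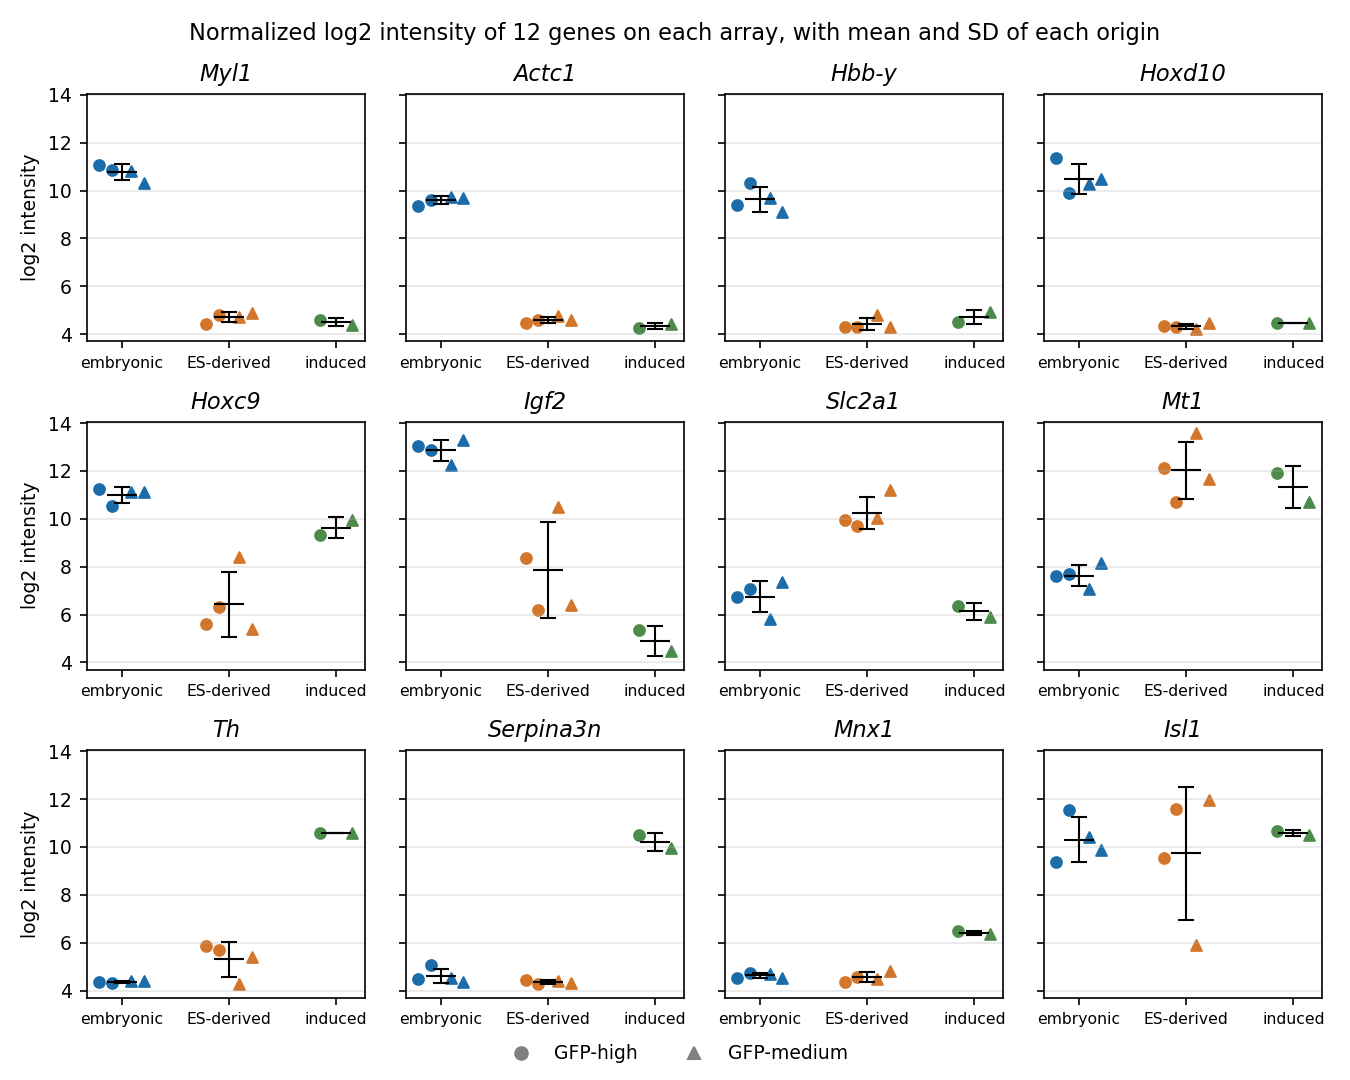
Normalized log2 intensity of 12 genes on each array by origin, with circles for GFP-high, triangles for GFP-medium and the mean with SD per origin. Myl1, Actc1, Hbb-y, Hoxd10 and Hoxc9 are highest on the embryonic arrays, Slc2a1 on the ES-derived and Th and Serpina3n on the induced arrays.

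The second comparison set motor neurons reprogrammed from fibroblasts against those of the embryo. In induced cells the muscle list was lower (6 of 14 members called), also with an estimated correlation, and the mesenchymal list (6 of 26 called) with the preset correlation only (adjusted p = 0.132 with an estimated correlation). The imprinted growth factor gene Igf2 (-7.96 ± 1.07, adjusted p = 0.00836) and Hoxd10 (at least 39.3-fold lower, adjusted p = 3.38e-04) fell. Induced cells had more RNA of Th, the rate-limiting enzyme of catecholamine synthesis (at least 48.2-fold, adjusted p = 3.38e-04), of the protease inhibitor gene Serpina3n (5.61 ± 0.37) and of the neuropeptide gene Gal (4.61 ± 0.85). Mnx1 was detected on both induced arrays and on 0 embryonic arrays, and was called higher (at least 2.66-fold, adjusted p = 0.0462). It is in the list of reprogramming factors, and the labels do not name those used here. RNA of an introduced copy therefore cannot be told apart from that of the cells' own gene. Of 9679 features, 123 were called, 43 higher and 80 lower, none with overlapping arrays (40.3% of all genes do not overlap with 2 arrays against 4). Without the dimmest array 646 were called (285 higher, 361 lower), and without the 3 dimmest 1682 (750 higher, 932 lower). Each set held all 123.

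Of 14 muscle genes, 6 fell (10 adjusted over the list alone; median -3.18, at bounds -2.76; camera adjusted p = 2.91e-17). Tnnt1 was at least 52.0-fold, Myl1 at least 47.9-fold, Myh8 at least 32.3-fold and Actc1 at least 21.2-fold lower. Of 26 mesenchymal genes, 6 fell (14 lower and 1 higher adjusted over the list alone), with a median of -1.51, at bounds -0.85 (camera adjusted p = 1.00e-12; adjusted p = 0.132 with an estimated correlation). They included Col5a1 (at least 33.3-fold), the proteoglycan gene Dcn (at least 17.3-fold), Pdgfra (-5.63 ± 0.87) and Mmp2 (-4.51 ± 0.71). The blood list was not called (adjusted p = 0.0626; 1 higher and 3 lower adjusted over the list alone), but was called lower without embryonic GFP-medium replicate 1 (0.0490), embryonic GFP-high replicate 2 (0.0341) or the induced GFP-medium array (0.00673) and with the authors' values (0.0495). Its globins Hbb-y and Hba-a1 fell (at least 21.7-fold and 8.63-fold) while Lyz2, the lysozyme of macrophages, rose (2.95 ± 0.47). The muscle, mesenchymal and globin genes named here were detected on all 4 embryonic arrays, and Pdgfra, Mmp2 and Igf2 on 1 induced array. Serpina3n was detected on 1 and Thy1 on 2 embryonic arrays.

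Of 27 cell cycle genes, 0 were called (6 lower adjusted over the list alone), with a median of -1.25, at bounds -0.79 (camera adjusted p = 6.41e-06; adjusted p = 0.528 with an estimated correlation). The centromere gene Cenpa stood at -3.15 ± 0.78 and the replication helicase gene Mcm4 at -3.00 ± 0.81. Without the dimmest array 7 members were called lower, and without the 3 dimmest 15 lower and 1 higher. Of 6 Hox paralogs 10 to 13, 1 fell, Hoxd10 (3 adjusted over the list alone; median -1.14, at bounds -0.37; camera adjusted p = 2.69e-04; adjusted p = 0.0548 with an estimated correlation). Hox paralogs 6 to 9 had 0 calls (camera adjusted p = 0.1998), with Hoxc9 at -1.36 ± 0.72. In the motor column list of 12 genes Alcam fell (-3.05 ± 0.61; 1 adjusted over the list alone), with a list median of -1.02, at bounds -0.66 (camera adjusted p = 0.00874; adjusted p = 0.132 with an estimated correlation). The 62 ribosomal protein genes had 0 calls (0 adjusted over the list alone) and a median of 0.59 (camera adjusted p = 1.77e-04; adjusted p = 0.528 with an estimated correlation).

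Other called genes, several of them neuronal, went both ways. The largest falls included the secreted neurexin ligand gene Nxph1 (at least 45.8-fold), the growth factor gene Ptn (at least 41.3-fold) and Tceal5 (at least 37.2-fold). The glycine receptor gene Glra2 was at least 21.2-fold lower, and Slc17a6, a vesicular glutamate transporter gene, fell by 4.68 ± 0.85. Rises included Rgs4, a regulator of G protein signalling (4.33 ± 0.85), R3hdm1 (at least 11.7-fold), the calcium buffer gene Pvalb (3.53 ± 0.41) and the surface glycoprotein gene Thy1 (2.91 ± 0.37). The pan-neuronal list held 1 call of 19 (1 adjusted over the list alone; camera adjusted p = 0.300), and was called higher without the induced GFP-high array (0.0362). Without embryonic GFP-medium replicate 1 the other spinal neuron list was called lower (0.0269). The immediate early list was called lower without embryonic GFP-high replicate 2 (0.00769). Isl1 stood at 0.28 ± 1.42 and Chat at 0.25 ± 1.12, while Lhx3 was detected on 0 induced arrays and 1 embryonic array. Neither the motor neuron transcription factors (adjusted p = 0.896) nor the cholinergic genes (0.660) were called.

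Of 26 lists 7 were called, 1 with the estimated correlation (muscle, adjusted p = 0.0316) and 5 with fry. Signs of median, mean and test differed for the motor neuron factor, progenitor, glial, reprogramming and X-linked and Y-linked lists, none called. The limma counts without 1 array were 48 (embryonic GFP-high replicate 1), 50 (embryonic GFP-high replicate 2), 43 (embryonic GFP-medium replicate 2), 646 (ES-derived GFP-high replicate 1), 10 (induced GFP-high) and 13 (induced GFP-medium). They were 27 (8 higher, 19 lower) with median scaling, which moved the median of all genes from -0.02 to 0.31. They were 3135 with array weights, 0 with gate means as replicates, and 126 (27 higher, 99 lower) with the authors' values.

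The third comparison set both in vitro products against each other. Induced cells had less RNA of glycolysis genes than ES-derived cells, with the hexokinase gene Hk2 at -6.10 ± 1.07 (adjusted p = 0.0350), Slc2a1 at -4.11 ± 0.58, Pfkl at -3.82 ± 0.48 and Slc2a3 at -3.44 ± 0.56. Serpina3n (at least 17.2-fold), Rgs4 (5.53 ± 0.85), Gal (5.39 ± 0.85) and Th (5.29 ± 0.45) were higher. With values not detected set to the lowest detected value of their array, Rgs4 stood at 4.82, Gal at 4.33 and Th at 4.26. The growth factor gene Mdk (-4.84 ± 0.41), the methyltransferase gene Prmt8 (-4.95 ± 0.57), the hormone gene Sct (-4.73 ± 0.72), Tceal5 (at least 25.8-fold) and Fblim1 (at least 10.4-fold) were lower. Of 9679 features 78 were called, 54 higher and 24 lower, none with overlapping arrays (21.3% of all genes). Without the dimmest array 399 were called (214 higher, 185 lower), and without the 3 dimmest 1099 (504 higher, 595 lower). Each set held all 78. Hk2 and Sct were detected on 1 induced array, Th on 2 and Rgs4 and Gal on 3 ES-derived arrays.

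Of 17 glycolysis and hypoxia genes, 4 fell (6 adjusted over the list alone; median -0.88; camera adjusted p = 1.23e-06). The 27 cell cycle genes had 0 calls (6 lower adjusted over the list alone), with a median of -0.91, at bounds -0.50 (camera adjusted p = 1.23e-06; adjusted p = 0.475 with an estimated correlation). Plk1, a mitotic kinase gene, stood at -2.99 ± 0.90. The 12 pluripotency genes had 0 calls (0 adjusted over the list alone), with a median of -2.70, at bounds -2.21 (camera adjusted p = 1.21e-04; adjusted p = 0.475 with an estimated correlation). Dppa4 (at least 13.7-fold lower, adjusted p = 0.180) and Sall4 (at least 9.60-fold lower, adjusted p = 0.276) were not detected on either induced array. ES-derived GFP-medium replicate 1 held the highest values of both. Pan-neuronal genes had 1 call of 19 (1 adjusted over the list alone), Thy1 (at least 2.88-fold higher), with a median of 0.92, at bounds 0.91 (camera adjusted p = 0.0349; adjusted p = 0.655 with an estimated correlation). That list call was lost without ES-derived GFP-medium replicate 1 (adjusted p = 0.451), ES-derived GFP-high replicate 2 (0.261) or the induced GFP-medium array (0.557).

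Of the Hox lists, the anterior one was called lower and the middle one higher. The 12 paralogs 1 to 5 had 0 calls (0 adjusted over the list alone), with a median of -0.76, at bounds -0.63 (camera adjusted p = 0.00359; adjusted p = 0.475 with an estimated correlation), and Hoxd4 stood at -3.26 ± 0.90. The 9 paralogs 6 to 9 had 0 calls (1 higher adjusted over the list alone), with a median of 1.16 (camera adjusted p = 0.0170; adjusted p = 0.475 with an estimated correlation), and Hoxc9 stood at 3.21 ± 0.72. The latter call was lost without ES-derived GFP-high replicate 2 (adjusted p = 0.0704) or the induced GFP-medium array (0.113). Kcnj12, a potassium channel gene, rose by 4.36 ± 0.73 (detected on 2 ES-derived arrays), and Lyz2 was at least 4.09-fold higher, while the blood list was not called (adjusted p = 0.265; 2 higher adjusted over the list alone), but was called higher without the induced GFP-high array (0.0235). The ribosomal list (0.278) was called higher with no filter on dim probes (0.0309), without the dimmest array (0.0120) and without the 3 dimmest (1.28e-04). Without the dimmest array the synaptic list was called higher (0.0118) and the stress list lower (0.0436). The motor column list was called lower without ES-derived GFP-medium replicate 1 (0.0319). The muscle (0.258) and mesenchymal (0.653) lists were not called. Mnx1, detected on both induced arrays and on 0 ES-derived arrays, was not called (at least 1.23-fold higher, adjusted p = 0.0522), and Isl1 stood at 0.84 ± 1.42 and Chat at -0.42 ± 1.12.

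Of 26 lists 7 were called, 1 with the estimated correlation (glycolysis, adjusted p = 0.0313) and 3 with fry. Signs of median, mean and test differed for the ion channel, mesenchymal, interferon and X-linked and Y-linked lists, none called. The limma counts without 1 array were 46 (embryonic GFP-high replicate 1), 42 (embryonic GFP-high replicate 2), 38 (embryonic GFP-medium replicate 2), 399 (ES-derived GFP-high replicate 1), 50 (ES-derived GFP-medium replicate 2), 1 (induced GFP-high) and 10 (induced GFP-medium). They were 6 (6 higher, 0 lower) with median scaling, 1581 with array weights and 0 with gate means as replicates. The median log2 difference of all genes was 0.08, and 0.23 with the authors' values.

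**Figure D3:**
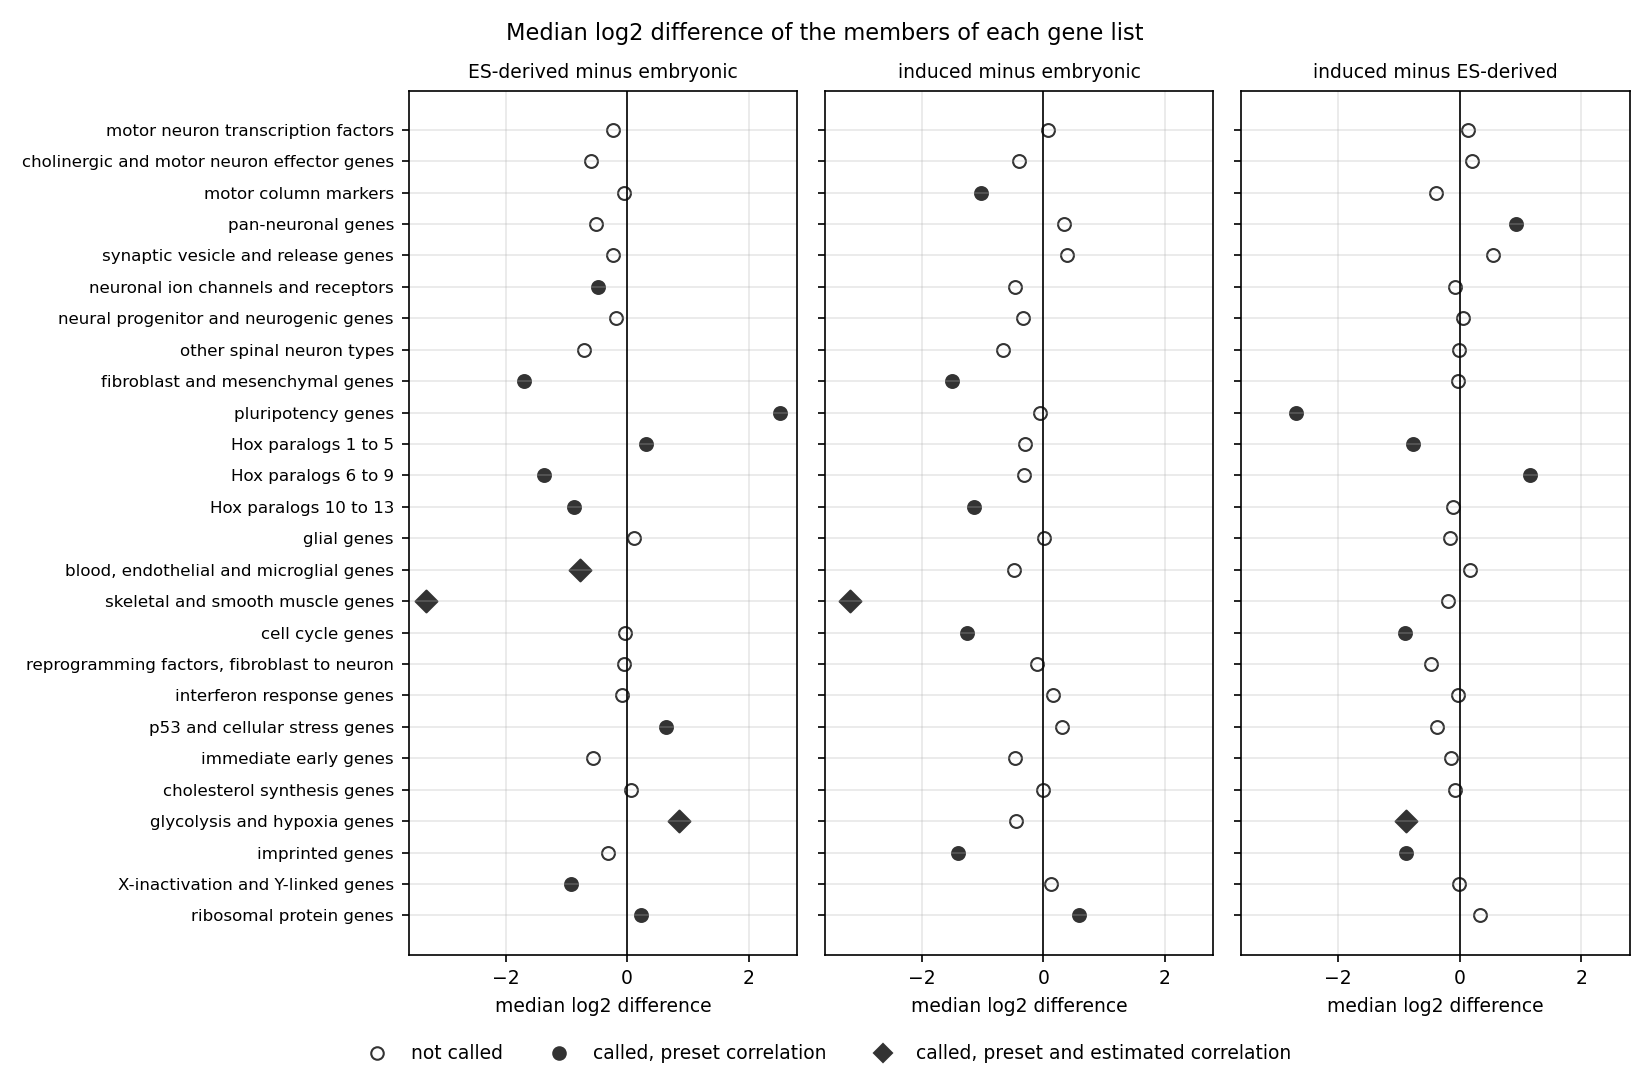
Median log2 difference of each of the 26 gene lists in the 3 comparisons of origins. Open symbols mark lists not called, filled circles those called with the preset correlation and diamonds those called with the estimated correlation as well: muscle, blood and glycolysis genes in ES-derived against embryonic cells, muscle genes in induced against embryonic cells and glycolysis genes in induced against ES-derived cells.

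Between the GFP gates no single gene was called, and 5 lists were called with the preset correlation only. All 19 pan-neuronal genes were positive in GFP-high minus GFP-medium (median 0.67; camera adjusted p = 5.65e-07), with Stmn2, a regulator of neuronal microtubules, at 1.48 ± 0.51 and the RNA-binding protein gene Elavl4 at 1.30 ± 0.56. The 14 synaptic genes had a median of 0.54 (adjusted p = 9.40e-04), with Syt4 at 1.18 ± 0.46. The 27 cell cycle genes had a median of -0.67 (adjusted p = 1.81e-06), with Plk1 at -2.10 ± 0.66. The 16 progenitor genes had a median of -0.43 (0.0240) and the 12 pluripotency genes one of -0.87 (0.0283). In each of these lists 0 members were called, also adjusted over the list alone, and all 5 calls were lost with the estimated correlation (adjusted p = 0.640 with an estimated correlation, for each). Chat stood at 1.35 ± 0.81, and the cholinergic list was not called (adjusted p = 0.101), but was called higher without embryonic GFP-high replicate 1 (0.0208) or GFP-medium replicate 1 (0.0163). The ribosomal list (0.108) was called lower with no filter (0.00208), and without ES-derived GFP-high replicate 1 (2.41e-06), embryonic GFP-medium replicate 2 (0.0125), ES-derived GFP-medium replicate 2 (0.0151) or either induced array (0.0366). The ion channel list (0.0606) was called higher without embryonic GFP-high replicate 2 (0.0275), ES-derived GFP-medium replicate 2 (0.0428) or either induced array (0.0368), and the immediate early list without embryonic GFP-high replicate 2 (0.0276).

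The pan-neuronal and synaptic differences were largest in ES-derived replicate 1, whose GFP-high array is the dimmest and whose GFP-medium array had high pluripotency values. That pair of arrays gave pan-neuronal genes a median gate difference of 3.44, against 0.16 in ES-derived replicate 2, 0.10 in the induced cells, and -0.16 and 0.56 in the embryonic replicates 1 and 2. For cell cycle genes the medians were -1.13 in ES-derived replicate 2, 0.09 in the induced cells, and 0.52 and -0.37 in the embryonic replicates 1 and 2. The ES-derived replicate 1 pair could not measure them: 3 of 27 were detected on its GFP-high array, and the median of -3.02 became 0.52 with values not detected set to the lowest detected value of their array. Of the 12 pluripotency genes 2 and of the 16 progenitor genes 0 were detected on that array. The cell cycle call was not lost when any 1 array was left out. Without ES-derived GFP-high replicate 1 the pan-neuronal (adjusted p = 0.110) and synaptic (0.138) calls were lost. The progenitor call was lost without embryonic GFP-medium replicate 2 (0.0553), ES-derived GFP-high replicate 2 (0.326) or ES-derived GFP-medium replicate 2 (0.194). The pluripotency call was lost without embryonic GFP-medium replicate 2 (0.0522), ES-derived GFP-medium replicate 1 (0.472) or ES-derived GFP-high replicate 2 (0.487), and with the authors' values (0.0507). Without ES-derived GFP-high replicate 2, 3 lists were called. Without the 3 dimmest arrays the pan-neuronal (0.0682), synaptic (0.0514) and pluripotency (0.0682) calls were lost. Signs of median, mean and test differed for 8 lists, none called: motor neuron factor, motor column, other spinal, mesenchymal, Hox 1 to 5, Hox 6 to 9, reprogramming and glycolysis genes.

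With limma, 0 genes were called between gates (201 at an unadjusted p under 0.05, smallest adjusted p = 0.962), and fry called 0 lists. The gate differences of embryonic replicates 1 and 2 correlated at -0.301 across genes. The missing calls therefore do not show that the gates are alike. The gate difference changed with origin for 0 genes in each contrast: 156 had an unadjusted p under 0.05 for ES-derived against embryonic cells, 21 for induced against embryonic and 114 for induced against ES-derived. Without ES-derived GFP-high replicate 2, which leaves the dimmest array as the only one of its group and assumes that it varies like the others, the first of these contrasts had 1406 calls and the last 423.

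Called genes overlapped between both comparisons with embryonic cells, which share the 4 embryonic arrays. Of the 87 and 123 called genes, 48 were shared, and 47 of these were lower in both. They included Myl1, Actc1, Myh8, Hoxd10, Hbb-y, Pdgfra and Igf2. Nfib was lower in ES-derived cells (-1.98) and higher in induced cells (2.07), as the only gene of opposite direction. Independent lists of these sizes would share 0.653 genes lower in both, a value that leaves out the shared arrays. Simulated unchanged groups, with every array drawn anew and the same simulated embryonic arrays in both comparisons, shared at most 0 in 20 draws. That value leaves out the real differences, so the excess over either is not the number of genes shared apart from those arrays. With separate embryonic replicates for each comparison, 7 genes were shared in the same direction under either assignment. These fits called fewer genes: 11 or 14 for ES-derived cells, by assignment, and 28 for induced cells under either. Without the dimmest array the count shared in the same direction was 118, and without the 3 dimmest 224. Across genes the differences had r = 0.419, against 0.409 in these simulated groups. The covariance of the differences was 0.332 against 0.192 simulated, a difference of 0.140. The simulated noise was the residual spread of each gene over all arrays, the dimmest included, and not that of the embryonic arrays. Neither simulated value therefore measures what the shared embryonic arrays alone give. With separate embryonic replicates r was 0.240 and 0.375, with covariances of 0.218 and 0.307. Genes are not independent replicates.

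Profiles were most alike within the embryonic and induced origins. The mean correlation across genes was 0.938 ± 0.0240 (SD, 6 pairs) among embryonic arrays and 0.704 ± 0.167 (SD, 6 pairs) among ES-derived arrays. It was 0.964 for the pair of induced arrays, which are 1 per gate without a replicate. Between origins it was 0.854 ± 0.0136 for embryonic with induced (8 pairs), 0.789 ± 0.122 for embryonic with ES-derived (16 pairs) and 0.772 ± 0.107 for ES-derived with induced (8 pairs). Without ES-derived GFP-high replicate 1 the mean was 0.853 for embryonic with ES-derived, 0.827 for ES-derived with induced and 0.853 among ES-derived arrays.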

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

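The tests of a dim array and of undifferentiated cells were chosen after the result was seen. Values of a gene or list mean on a single array were set apart when their gap to the nearest of the other 3 arrays of the origin was large against the range (Dixon's test). Of 262 values tested, 21 were set apart, and chance sets apart about 1 in 20 such groups.

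Among embryonic arrays, GFP-medium replicate 1 gave Cdk2 a log2 value of 8.33 (others 9.81 to 10.05), Dppa5a 6.36 (4.89 to 5.13), Hoxa2 5.02 (6.08 to 6.25) and Rpl24 6.48 (5.12 to 5.24). GFP-medium replicate 2 gave Hoxd4 9.26 (7.23 to 7.53). GFP-high replicate 1 gave Dppa4 5.32 (4.29 to 4.43), and GFP-high replicate 2 gave Th 4.30 (4.38 to 4.38), both near the floor. Hoxa2 and Th were not detected on these arrays.

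Among ES-derived arrays, GFP-medium replicate 1 stood apart most often. Its list means were 5.88 for fibroblast and mesenchymal genes (others 4.82 to 4.98) and 6.46 for interferon response genes (5.02 to 5.26). Its Dcx value was 5.25 (others 9.20 to 10.01), Ifitm1 9.73 (4.26 to 4.80), Alcam 7.38 (6.08 to 6.25), Hoxc10 5.17 (4.26 to 4.39) and Hbb-y 4.78 (4.29 to 4.30). GFP-high replicate 1, the dimmest array, had a p53 and stress list mean of 6.69 (7.85 to 8.02), Rrm1 at 4.40 (8.54 to 9.11) and Hba-a1 at 5.73 (4.24 to 4.30). GFP-high replicate 2 had Ddit4 at 8.15 (9.96 to 10.11) and Isl2 at 6.26 (4.50 to 4.51). GFP-medium replicate 2 had Lhx5 at 6.96 (4.27 to 4.37) and Nes at 7.03 (4.197 to 4.40). Ifitm1, Isl2, Lhx5 and Nes were not detected on the other ES-derived arrays, so the ranges given for them are not levels. The Dcx, Hoxc10, Hbb-y, Rrm1 and Hba-a1 values were below the lowest detected value of their array (5.55 on GFP-medium replicate 1, 8.68 on GFP-high replicate 1), so they are not levels, and the list means hold such values too.

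Pluripotency genes were high on ES-derived GFP-medium replicate 1, with Dnmt3l at 12.55, Dppa5a at 12.48 and Nanog at 12.36. The dimness of that array stays open: the list medians on both dimmer arrays lay below those of the arrays compared (larger median difference -0.369, log2), but on the dimmest a rise of 1 could be detected for only 3 of 12 genes, and Dppa5a (11.35) and Dppa4 (9.42) were higher there than on the replicate 2 arrays. Undifferentiated cells in the sorted fraction are a candidate explanation: against the ES-derived replicate 2 arrays, 11 of 12 pluripotency genes (median 3.24) and 25 of 27 cell cycle genes (median 1.34) were higher, and 18 of 19 pan-neuronal genes were lower, with a median of -1.67. A sort on GFP would remove cells without the reporter, and the values do not show how such cells would have entered. A difference between differentiations stays open and was not tested.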

How the results depend on the processing

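Fits without the 3 dimmest arrays, the shared genes without ES-derived GFP-high replicate 1 and the list medians with median scaling were chosen after the data were seen. The counts of called genes follow in the order ES-derived against embryonic, induced against embryonic and induced against ES-derived. They were 87, 123 and 78, and stayed within 1.5 times of that without background correction, with the authors' values, no filter, detection on at least 4 arrays, all probes, a trended and robust variance, a fold of at least 2 and a random replicate block. Median scaling gave 40, 27 and 6. Array weights gave 550, 3135 and 1581, with the dimmest array weighted 0.0772. GFP-high arrays alone gave 0, 0 and 0, GFP-medium arrays alone 2, 0 and 0, and means of both gates 0, 0 and 0, each with fewer arrays. Without the 3 dimmest arrays the counts were 409, 1682 and 1099. Leaving out each array gave 35 to 270, 10 to 646 and 1 to 399. Only the embryonic and ES-derived arrays gave 55. The cause of these changes was not tested. Without ES-derived GFP-high replicate 1 the log2 differences of induced against embryonic cells correlated at 1 with those of all arrays. Calls rose from 123 to 646, so the change there lay in the estimated spread and not in the differences.

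Replicate numbers were shared between groups, and whether they paired the samples stays open. Correlations across genes of deviations from group means lay between -0.0905 and 0.204. Yet Xist and Eif2s3y differed less between same-numbered than between crossed embryonic gates, with ratios of 0.263 and 0.415. With the number as a fixed replicate block over embryonic and ES-derived arrays, 37 genes were called. A random replicate block of origin and number (consensus correlation 0.110) gave 71, 89 and 57.

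For the gates 0 genes were called in every setting run. The gate difference changed with origin for 0 to 1406 genes (ES-derived against embryonic) and 0 to 423 (induced against ES-derived) when an array was left out. Called lists numbered 12, 7, 7 and 5 (gates last), and 3, 1, 1 and 0 with an estimated correlation. For the gates they were 3 to 7 without 1 array and 3 without the 3 dimmest. In that setting the cell cycle list turned lower in ES-derived against embryonic cells (adjusted p = 0.00739) and the other spinal neuron list turned lower in GFP-high cells (adjusted p = 9.81e-04). Lists were not tested with median scaling or array weights, but their medians were computed with median scaling. Genes shared in the same direction by both comparisons with embryonic cells numbered 47. They numbered 118 without ES-derived GFP-high replicate 1 and 224 without the 3 dimmest arrays. Under either split of the embryonic arrays they numbered 7, with only 11 or 14 genes called for ES-derived and 28 for induced cells. The mean correlation of embryonic with induced arrays was 0.811 and that of the induced pair 0.935 with the authors' values, and the former was 0.904 with no filter. The cause was not tested.

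Of 5580 values of single named genes under alternatives, 4766 kept direction and side of the threshold, 170 passed it anew and 564 no longer did, and 80 had the other sign and were called in neither setting. For lists the numbers were 1448, 38, 59 and 117, with 2 reversed. Low signal limits the dim arrays: the lowest detected log2 value was 8.68 on ES-derived GFP-high replicate 1.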

Other observations

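The tests of exchanged gate labels, of crossed replicate numbers and of array brightness were chosen after the result was seen. The second tissue marker lists, the scaling test and the counts over other splits were set before theirs.

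Of 14 imprinted genes measured, several of which act on fetal growth, Igf2 and Ndn (-3.68 ± 0.47) fell in induced against embryonic cells, with a list call under the preset correlation only (5 lower adjusted over the list alone; median -1.41, at bounds -1.21; camera adjusted p = 2.69e-04; adjusted p = 0.0548 with an estimated correlation). Against ES-derived cells Ndn fell by 3.05 ± 0.47 (1 adjusted over the list alone; median -0.88, at bounds -0.79; adjusted p = 0.00685; adjusted p = 0.185 with an estimated correlation). In ES-derived against embryonic cells Igf2 fell by 4.98 ± 0.87 (3 lower adjusted over the list alone) and the list was not called (adjusted p = 0.176; 0.0188 without the 3 dimmest arrays). The Y-linked gene Eif2s3y was not detected on any ES-derived array, and was at least 2.88-fold lower there than in embryonic cells and at least 7.51-fold higher in induced than in ES-derived cells. Xist was detected on all 4 embryonic arrays, on 1 ES-derived array and on 0 induced arrays. The list of 4 X-inactivation and Y-linked genes was called lower in ES-derived against embryonic cells (median -0.92, at bounds -0.20; 2 lower adjusted over the list alone; adjusted p = 0.0281; adjusted p = 0.141 with an estimated correlation). That call was lost without ES-derived GFP-high replicate 2 (0.120) or GFP-medium replicate 2 (0.121).

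Stress genes were called higher as a list of 20 in ES-derived against embryonic cells (median 0.64; 0 members called, 0 adjusted over the list alone; camera adjusted p = 0.00189; adjusted p = 0.0697 with an estimated correlation), with the asparagine synthetase gene Asns at 1.71 and the transcription factor gene Atf4 at 1.61. The 62 ribosomal protein genes were called too (median 0.22, at bounds 0.17; 0 members called, 0 adjusted over the list alone; camera adjusted p = 7.83e-04; adjusted p = 0.481 with an estimated correlation). That call was lost without ES-derived GFP-high replicate 1 (0.164), without the 3 dimmest arrays (0.398) and with no filter on dim probes (0.0757), and with median scaling the list median (0.09) lay below that of all genes (0.13). Immediate early (adjusted p = 0.215), cholesterol synthesis (0.293) and interferon (0.594) lists were not called in that comparison. The first was called lower without embryonic GFP-high replicate 2 (0.0367) and the second higher without the 3 dimmest arrays (0.0182).

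The gate difference on the embryonic arrays ran in opposite directions in replicates 1 and 2. GFP-high minus GFP-medium was -2.45 and 2.65 for Chat, -2.86 and 3.58 for Slc10a4 and 1.62 and -3.79 for the progenitor gene Nes, and the correlation across genes of both replicates' differences was -0.301. Array brightness stays open for replicate 1, whose arrays differed 9.25-fold in mean intensity; in replicate 2, with a ratio of 0.8003, the median absolute difference of 44 neuronal genes was 1.38 times that in replicate 1, which bears on replicate 2 alone. The replicate 2 difference correlated with ES-derived replicates 1 and 2 and the induced pair at 0.188, 0.323 and 0.108, and that of replicate 1 at -0.121, -0.0303 and -0.0282, so that exchanged gate labels in replicate 1 cannot be told apart from a difference between preparations: the values of replicate 1 are all negative, but 2 of them lie near 0. Crossed replicate numbers stay open as well, since only 2 sex-linked genes could be used, with a ratio of same-number to crossed differences of at most 0.415.

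Muscle, mesenchymal and globin genes were high on the embryonic arrays against both in vitro products. With median scaling all 30 called tissue gene differences stayed at 1 or more (log2). Normalization between arrays stays open all the same. The differences were picked as called with quantile normalization, where the smallest call was 1.56 (ES-derived) or 1.78 (induced). Both scalings also followed the same background correction. Cells or RNA of neighbouring tissues in the sort may contribute. All 25 second-list markers tested were higher in embryonic than in induced cells (median 1.20). Of these, 4 of 7 muscle, 2 of 3 erythroid and 14 of 15 mesenchyme and cartilage markers were higher than in ES-derived cells (median 0.787). The detection filter left 7 of 12, 3 of 10 and 15 of 22 markers on the array, and only 6 were detected on an induced array. A marker could pass through the embryonic arrays alone. The count of 25 and its median are therefore partly set by the filter, and most induced values are not levels. Embryonic levels were 9.69 for Matn4 (4.69 above induced cells), 8.94 for Igfbp4 (4.10 above) and 10.01 for Mfap2 (1.13 above). Whether such cells or RNA contribute stays undecided. Of the 25 markers, 0 are in another list, but 6 were also detected on an induced array and 14 on an ES-derived array. The muscle markers, with the lowest list median, differed by 0.593, and a sort on GFP would remove such cells. A difference of the motor neurons themselves was not tested apart from such cells.

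Other splits of the arrays were counted as well. For ES-derived against embryonic cells 1 of 35 splits, the real one, gave 87 genes and the highest other gave 0. This does not exclude chance, since 1 of 35 is the smallest share possible. It also holds only if the arrays of both gates are independent samples, which stays open. Other splits mix both origins, which adds the difference between them to the spread. With gate means as replicates, which leaves 2 for each of these origins, 0 genes were called. Nor can chance be excluded for the lists, with 12 in the real split, 12 in the highest other and 4 of 35 splits as large. For the gates it cannot be excluded for lists (5 in the real split, 14 in the highest other, 49 of 100 splits as large). For genes the real split gave 0 and the highest other 3430, so that 100 of 100 splits were as large by construction, which says nothing about chance. The split with 3430 genes points to a structure of the samples: it parts ES-derived GFP-high replicate 1 from the other ES-derived arrays.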
